A study of Mus musculus with 29 samples.

How the data were processed

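RNA-seq libraries were made from total RNA of mouse digits with a poly(A), strand-specific kit, 500 ng of RNA and 9 PCR cycles. The deposited tables hold raw counts per gene and library, as the authors made them; the aligner and the counting tool are not given in the sources used here. The genome build is GRCm39 per the submitters' processing notes. The time course table lists 24411 gene symbols in 17 libraries and the one for amputation lists 55487 Ensembl gene identifiers in 12 libraries. GENCODE M21, an annotation of GRCm38, served only for gene names and transcript lengths, and no coordinates were used; it gave a symbol for 55141 identifiers (99.4%). All columns were matched to a sample. The labels call the samples biological replicates. The unamputated samples are described as tissue that was not regenerated, with a time in days after amputation and a regenerate tissue tag, and were placed by their treatment label.

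The 2 tables were fitted apart, each with a mean per group (surgery and day, or amputation and day). Genes were filtered by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 16084 and 17475 genes holding at least 99.98% and 99.95% of the counts of each library. Counts were normalized by TMM and fitted with the quasi-likelihood model of edgeR with robust dispersions (common biological coefficient of variation 0.393 and 0.17). Contrasts were SNI against sham at each day and averaged over days with equal weight per day, amputated against unamputated in the same way, the interactions with day, and later days against day 7 within each group. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. Values of CPM in the text use the TMM-scaled library size.

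The lists of genes were of Schwann cell, nerve, skeletal, connective tissue, skin, vascular, muscle, fat, immune and stress groups, and those with at least 3 tested members were tested. Each list was tested by camera of limma with a preset correlation of 0.01, with the correlation estimated from the residuals as an alternative, and by fry. A list score, the mean log2 CPM (prior count 2) of its tested genes per library, was fitted by limma with moderated variances over lists and given with 95% intervals. Adjusted p values of lists cover the lists of a contrast. An adjusted p over the list alone corrects the gene p values within that list only.

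Named genes were those called with a mean CPM of at least 1, no overlap of libraries between the groups (within each day for averages) and no predicted gene model: the 10 with the largest rise and the 10 with the largest fall, or 5 each way for changes with time. Where fewer than 5 genes were called, the 5 with the smallest p were named as uncalled. Up to 4 members with the smallest p of a described list were added. Some genes that met this rule are not reported here. For 3 libraries against 3, chance alone separates 10% of genes without overlap.

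Alternatives were RLE size factors, no filter on low counts, DESeq2, limma voom with sample quality weights, a fit of the compared groups alone, replicate number as a block, and each library left out in turn. Where 1 library remained in a group, it was assumed to vary like the other groups. The groups, contrasts, lists, rule for named genes and these alternatives were fixed before the data were examined. Added after seeing the data were the time course without both libraries with a TMM factor under 0.8, 1 surrogate variable from svaseq as covariate, and the SNI average over days 7 and 21 only.

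The procedure was tested on simulated data, drawn with the means, dispersions and library sizes of the real ones. In the time course design at day 7 it recovered 8.96% of genes changed 2-fold, 61.2% of those changed 4-fold and 78.8% of those changed 8-fold, with 1 false call of 100. In the amputation design at day 7 it recovered 71.6%, 98.5% and 98.5%, with 8 false calls of 187. Only genes with a mean CPM of at least 1 were changed, and no other contrast was simulated. Camera gave the changed lists p values of 7.53e-15 and 4.71e-94, and 7 and 6 of 200 unchanged lists had a p under 0.05. The lists were random and the simulated genes varied independently, so this does not test camera on genes that vary together. For the same reason the recovery and false calls of genes may differ in the real libraries. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.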

Results

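Poly(A) RNA was sequenced from 29 libraries of mouse digit tissue, taken beyond the metacarpophalangeal joint with the nail removed, in 10 groups. A time course compared animals after spared nerve injury (SNI), a surgery that severs the tibial and common peroneal branches of the sciatic nerve, with sham-operated animals. The digit tip was amputated 5 days after surgery. It held sham libraries at day 7 (n = 3), day 14 (n = 3) and day 21 (n = 2) after amputation and SNI libraries at day 7 (n = 3), day 14 (n = 3) and day 21 (n = 3). Total counts were between 35654192 and 56809440 per library. A second set compared SNI digits with amputation (n = 3 at day 7, n = 3 at day 14) and without it (n = 3 at day 7, n = 3 at day 14), with totals between 31274245 and 43315729. The treatment labels of the last 2 groups say that no amputation was done, while their time and tissue labels name days after amputation and a regenerate digit. The treatment label was followed here.

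The first comparison addresses which genes differ between SNI and sham digits during regeneration. Averaged over the 3 days, Schwann cell myelin genes, which build the sheath around peripheral axons, fell in SNI digits. The score of that list, the mean of its 17 genes in log2 CPM (counts scaled by library size), fell by 1.17 (95% interval -1.65 to -0.70, adjusted p = 0.00428 by limma, 9 SNI and 8 sham libraries). Of the 17 genes, 16 had a negative fold change, 11 of them passed with a negative sign when adjusted over the list alone and 0 passed when adjusted over all genes. Mbp, which codes for myelin basic protein, was at 41.7 CPM ± 23 (SD, n = 9) in SNI and 85.0 CPM ± 20 (SD, n = 8) in sham. Its log2 fold change was -1.15 ± 0.21 (SE), with an adjusted p of 0.00157 over the list alone and 0.288 over all genes. Ugt8a, an enzyme of myelin lipid synthesis, had a log2 fold change of -1.23 ± 0.25 (SE), Ncmap of -1.47 ± 0.30 and Gjc3 of -1.52 ± 0.36. The myelin score passed without any 1 of the 17 libraries in turn (adjusted p from 0.000346 to 0.0201). The camera test of the same list against all other genes gave an adjusted p of 1.33e-13 and an adjusted p = 0.155 with an estimated correlation.

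The T cell list also passed on its score in that average, which rose by 0.60 (95% interval 0.25 to 0.95, adjusted p = 0.0493 by limma). All 9 of its tested genes had a positive fold change and 1, Cd3e with 0.54 ± 0.15 (SE), passed when adjusted over the list alone. Removing any 1 of 15 of the 17 libraries, all except sham day 21 replicate 1 and SNI day 14 replicate 1, ended the call, with adjusted p up to 0.211. It also ended with RLE size factors (0.0624) and with a replicate block (0.283). The camera test gave an adjusted p of 0.000217 and an adjusted p = 0.155 with an estimated correlation. Among Schwann cell injury-response genes, Gap43, a growth-cone protein made by Schwann cells after denervation, had a log2 fold change of 1.16 ± 0.23 (SE) and passed when adjusted over the list alone (adjusted p = 0.00301) but not over all genes (0.288). The score of that list of 14 genes differed by -0.03 (95% interval -0.41 to 0.35), its mean fold change was -0.01 and its median 0.10. The Schwann cell identity list of 10 genes had a score difference of -0.23 (95% interval -0.80 to 0.34), with Sorcs1 at -1.59 ± 0.34 (SE) and Ngfr at 0.69 ± 0.37.

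Camera called 16 of the 37 lists in the average, 9 up and 7 down, and 0 of these with an estimated correlation (adjusted p from 0.155 to 0.74). Macrophage genes were among those up, with 13 of 13 positive, a median log2 fold change of 0.53 and 6 higher when adjusted over the list alone (adjusted p = 3.68e-05, adjusted p = 0.496 with an estimated correlation). Sweat gland genes were among those down, with 9 of 9 negative, a median of -0.55 and 2 lower when adjusted over the list alone (adjusted p = 0.000979, adjusted p = 0.267 with an estimated correlation). Without each library in turn the macrophage median ran from 0.41 to 0.80 and the sweat gland median from -0.70 to -0.29, the last without sham day 21 replicate 2. The others up were neutrophil, inflammatory cytokine, osteoclast, adipocyte, mast cell, B cell, interferon response and T cell genes. The others down were differentiated epidermis, basal keratinocyte, Wnt pathway, cartilage, Merkel cell and myelin genes. Of the 16 calls, 5 (myelin, T cell, macrophage, differentiated epidermis and sweat gland) stood without each library in turn. Averaged over days 7 and 21 only, 9 of the 16 calls ended, that of macrophage genes among them (adjusted p = 0.0766). The Wnt, cartilage, adipocyte and mast cell calls ended without sham day 21 replicate 2 (adjusted p up to 0.141). The neutrophil and inflammatory cytokine calls ended without sham day 21 replicate 1 (0.0565 and 0.136). The osteoclast call ended without sham day 21 replicate 1, SNI day 14 replicate 1 or SNI day 21 replicate 1 (up to 0.334). The Merkel cell, basal keratinocyte, B cell and interferon response calls each ended without any 1 of 6 to 9 libraries (up to 0.598). The blastema mesenchyme list had a score difference of -0.13 (95% interval -0.60 to 0.35), the osteoblast and osteocyte list -0.13 (95% interval -0.93 to 0.66) and the proliferation list -0.20 (95% interval -0.51 to 0.12), and none of these passed. The median log2 fold changes of the osteoblast and proliferation lists, 0.14 and 0.06, had the opposite sign to their scores.

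No single gene of the 16084 tested was called in the average by edgeR: 0 genes passed, with 2248 at an unadjusted p under 0.05 against 804 expected by chance. Genes varied together in these libraries, so such counts can lie far from 804 by chance. The excess alone does not establish an SNI effect, and at day 21 the count was 354, below that value. DESeq2 called 153 genes, 78 higher and 75 lower, and limma voom with sample quality weights called 0. The 5 genes with the smallest p, all uncalled, were Tmprss5, Mgp (log2 fold change 0.80 ± 0.13, SE), Mbp, Adcyap1r1 (0.68 ± 0.13) and Cx3cr1 (0.79 ± 0.15), each with an adjusted p of 0.288. Tmprss5 was at 0.0967 CPM ± 0.14 (SD, n = 9) in SNI and 0.255 CPM ± 0.064 (SD, n = 8) in sham; all SNI libraries of day 21 were at 0, which leaves its fitted average without a lower bound. Mgp, an inhibitor of calcification, was at 120.0 CPM ± 25 (SD, n = 9) in SNI and 68.2 CPM ± 18 (SD, n = 8) in sham. Without SNI day 7 replicate 1, or without SNI day 14 replicate 2, 2 genes were called, and with 1 surrogate variable as covariate 5 were called.

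**Figure D1:**
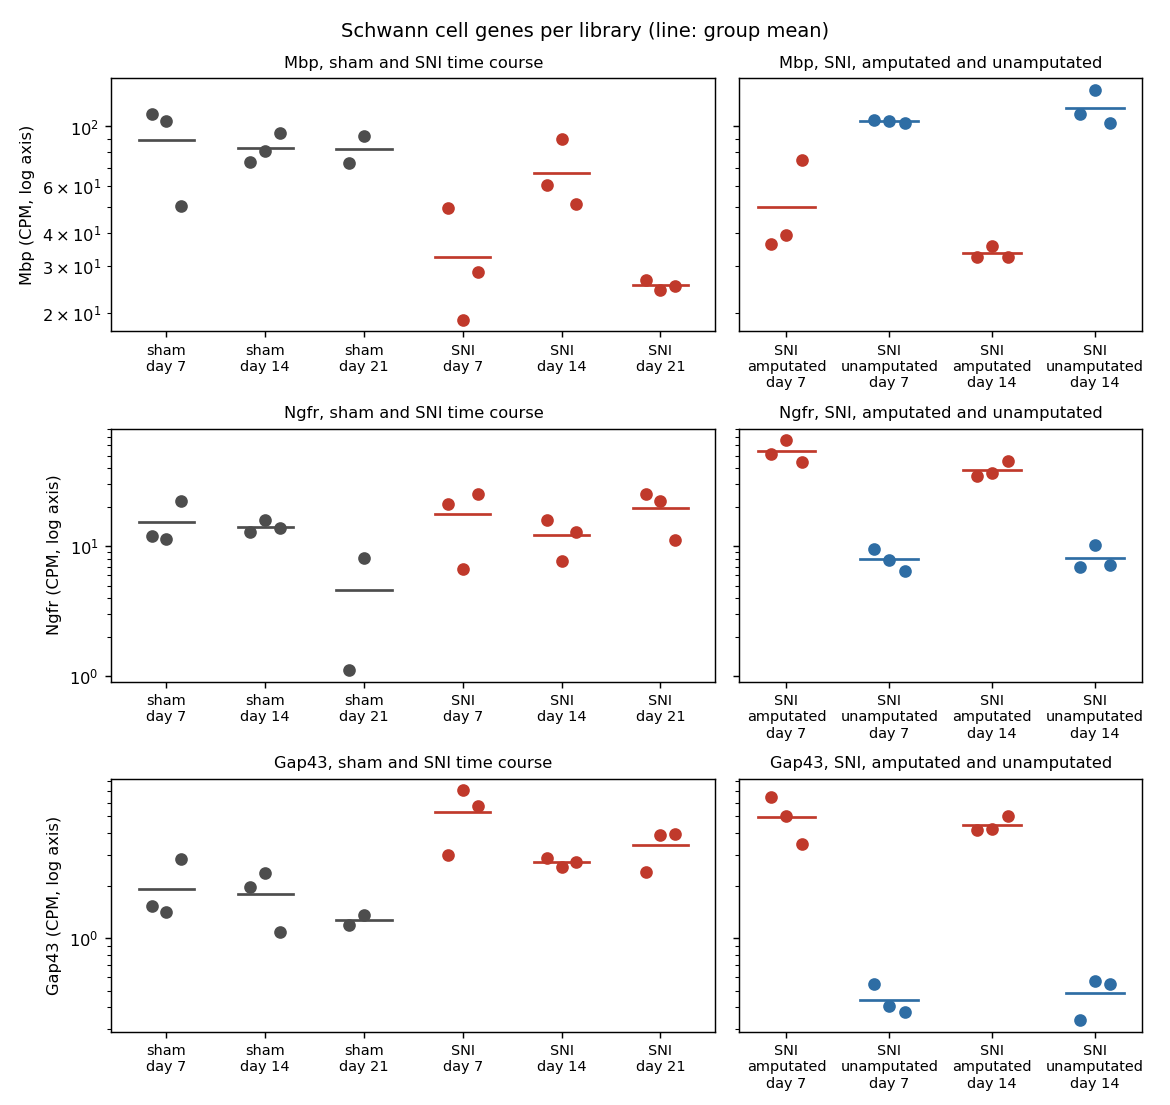
CPM on a log axis for Mbp, Ngfr and Gap43 in every library, by group, with the line at the group mean. Mbp lay between 103 and 137 CPM in the 6 unamputated SNI libraries and between 32.4 and 74.6 CPM in the 6 amputated ones.

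At day 7, the myelin list had 14 of 17 genes negative, with a median log2 fold change of -1.29. Camera called it down (adjusted p = 5.42e-05, adjusted p = 0.589 with an estimated correlation), 5 genes were lower when adjusted over the list alone and 0 over all genes. Its score differed by -1.38 (95% interval -2.18 to -0.59, adjusted p = 0.0813 by limma), which did not pass. All 10 neutrophil genes were positive, with a median of 6.73 and 9 higher when adjusted over the list alone (camera adjusted p = 0.00018, adjusted p = 0.589 with an estimated correlation). S100a8, an abundant protein of neutrophils, was at 4420 CPM in SNI day 7 replicate 2, a library that stood apart in composition, at 19.4 and 54.8 CPM in the other SNI libraries and at 5.05 to 12.5 CPM in sham. Without that library the neutrophil median was 1.04. Adipocyte genes were up by camera with 9 of 10 positive and a median of 1.45, and differentiated epidermis genes were down with 12 of 14 negative and a median of -0.58 (camera adjusted p of 0.00257 and 0.00094, each with an adjusted p = 0.589 with an estimated correlation).

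No list score passed at day 7, and edgeR called 0 genes, with 2191 at an unadjusted p under 0.05. DESeq2 called 40 genes and voom with quality weights 7749. The voom weights were 7.32 for sham replicate 2 and 4.71 for SNI replicate 3, against 0.171 to 1.29 for the other libraries of that day. The uncalled genes with the smallest p were Carns1 (log2 fold change -1.66 ± 0.37, SE), Gzma (4.48 ± 1.0), Lyve1 (-1.07 ± 0.24), Tmprss5 (-3.04 ± 0.66) and Otop1 (-2.63 ± 0.61), each with an adjusted p of 0.301. Gzma in sham (0.0571 CPM) and Tmprss5 and Otop1 in SNI (0.0274 and 0.085 CPM) had very low counts. The sizes of their changes are therefore uncertain. Lyve1, a marker of lymphatic endothelium, was at 15.1 CPM ± 1.2 (SD, n = 3) in SNI and 31.5 CPM ± 9.0 (SD, n = 3) in sham.

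At day 14, macrophage genes were up by camera in SNI digits, with 13 of 13 positive, a median log2 fold change of 1.47 and 10 higher when adjusted over the list alone (adjusted p = 6.51e-10, adjusted p = 0.43 with an estimated correlation). Cd68, a lysosomal protein of macrophages, had a log2 fold change of 1.48 ± 0.35 (SE) and C1qc, a complement subunit, of 1.47 ± 0.42. Osteoclast genes had 12 of 13 positive, a median of 2.63 and 9 higher when adjusted over the list alone (adjusted p = 7.41e-06, adjusted p = 0.539 with an estimated correlation), with Dcstamp at 3.74 ± 0.91 (SE) and Acp5 at 2.34 ± 0.57. Inflammatory cytokine genes had 10 of 10 positive, a median of 3.07 and 6 higher when adjusted over the list alone (adjusted p = 2.49e-05, adjusted p = 0.513 with an estimated correlation), with Il1b at 4.33 ± 1.3 (SE). Hard keratin genes had 13 of 13 negative with a median of -0.99 (camera adjusted p = 0.00144, adjusted p = 0.702 with an estimated correlation); without SNI day 14 replicate 1 the adjusted p was 0.0507. Without SNI day 14 replicate 3 the medians of these 4 lists were smaller, at 0.94 for macrophage, 1.60 for osteoclast, 1.80 for inflammatory cytokine and -0.56 for hard keratin genes, and the highest in size over the fits without 1 library were 1.70, 3.20, 3.39 and -1.81. The myelin list did not pass at this day, with a median of -0.38, a camera adjusted p of 0.0635 and a score difference of -0.49 (95% interval -1.29 to 0.30).

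No list score passed at day 14, and edgeR called 0 genes, with 954 at an unadjusted p under 0.05. DESeq2 called 61 genes, 58 higher and 3 lower, and voom with quality weights 8737. The voom weights were 0.227, 2.79 and 0.764 for SNI replicates 1, 2 and 3 and 2.45 to 3.41 for sham. The uncalled genes with the smallest p were AW551984 (log2 fold change 1.65 ± 0.30, SE), Pglyrp2 (1.83 ± 0.35), Epyc (1.68 ± 0.34), Tnfrsf9 (2.78 ± 0.57) and Igf1 (1.19 ± 0.24), each with an adjusted p of 0.555. Igf1, a growth factor, was at 57.6 CPM ± 9.3 (SD, n = 3) in SNI and 25.2 CPM ± 4.1 (SD, n = 3) in sham.

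At day 21, the myelin list fell in SNI digits, with 14 of 17 genes negative, a median log2 fold change of -1.69 and 10 genes lower when adjusted over the list alone, 0 over all genes. Camera gave an adjusted p of 2.64e-21, and the call held with an estimated correlation (adjusted p = 0.035 with an estimated correlation), the only list call of the time course that did. It ended with fry (adjusted p = 0.0694). Its score differed by -1.65 (95% interval -2.53 to -0.76, adjusted p = 0.0503 by limma), just over the threshold. Ncmap, a protein of noncompact myelin, was at 0.758 CPM ± 0.36 (SD, n = 3) in SNI and 6.08 CPM ± 2.1 (SD, n = 2) in sham, with an adjusted p of 0.00243 over the list alone and 0.766 over all genes. Tmprss5, a membrane serine protease, was listed at 0 in all 3 SNI libraries and at 0.248 CPM ± 0.055 (SD, n = 2) in sham, at least 9.79-fold lower at the limit of 3 counts over the SNI group, and it was uncalled (adjusted p = 0.517). Sox2 and Gap43 of the injury-response list passed when adjusted over the list alone, with log2 fold changes of 1.86 ± 0.55 (SE) and 1.43 ± 0.44. Immediate early and heat shock genes had 9 of 9 positive with a median of 0.83 (camera adjusted p = 0.000322, adjusted p = 0.533 with an estimated correlation), a call that ended without either sham day 21 library, with adjusted p up to 0.211; the median was 0.29 without sham day 21 replicate 1.

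At day 21 edgeR called 0 genes, with 354 at an unadjusted p under 0.05; DESeq2 called 12 genes and voom with quality weights 0. Without sham day 21 replicate 2, which leaves only replicate 1 in that group, 152 genes were called. The other uncalled genes with the smallest p were Gm6537 (log2 fold change -1.83 ± 0.32, SE), Ccdc96 (-2.51 ± 0.52) and Mstn (-1.90 ± 0.41), a muscle growth inhibitor.

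The test of whether the SNI effect differed between days called 0 genes by edgeR, with 588 at an unadjusted p under 0.05, 1 by DESeq2 and 21 by voom with quality weights; without sham day 21 replicate 2 it called 3439. Across the 16084 genes, which are not independent replicates, fold changes at day 7 and day 14 correlated with a Pearson r of 0.67. The r was -0.12 for day 7 with day 21 and -0.10 for day 14 with day 21, and the sign of these rests on the sham libraries of day 21. Without sham day 21 replicate 1 they were 0.57 and 0.48, without its replicate 2 -0.53 and -0.44, and without both low-factor libraries 0.51 and 0.48. That of day 7 with day 14 ran from 0.56 to 0.73 without each library in turn and was 0.38 with 1 surrogate variable.

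Within the sham group from day 7 to day 14, osteoclast genes were down by camera, with 11 of 13 negative and a median of -1.92 (adjusted p = 7.79e-16, adjusted p = 0.127 with an estimated correlation). Macrophage genes were down with 13 of 13 negative and a median of -0.74 (adjusted p = 4.34e-11, adjusted p = 0.159 with an estimated correlation). Osteoblast and osteocyte genes had 15 of 15 positive with a median of 0.84, and hard keratin genes of nail and hair 13 of 13 with a median of 1.13 (each with an adjusted p = 0.244 with an estimated correlation). Without each library in turn these medians ran from 0.55 (without sham day 7 replicate 3) to 1.00 and from 0.86 to 1.81. Within SNI over the same days, neutrophil genes had 10 of 10 negative with a median of -6.44 and myelin genes 15 of 17 positive with a median of 1.05 (each with an adjusted p = 0.292 with an estimated correlation). Without SNI day 7 replicate 2 the neutrophil median was -0.79, with 7 negative and 3 positive, and the myelin median 0.56. Tendon genes in SNI had 8 of 8 positive on both intervals, with medians of 0.91 to day 14 and 0.83 to day 21 (adjusted p = 0.453 and adjusted p = 0.541 with an estimated correlation). Without each library in turn these ran from 0.42 (without SNI day 14 replicate 1) to 1.79 and from 0.15 (without SNI day 21 replicate 1) to 1.83. In sham from day 7 to day 21, immediate early and heat shock genes had 9 of 9 negative with a median of -0.87 (camera adjusted p = 0.00215, adjusted p = 0.8 with an estimated correlation); without sham day 21 replicate 2 the adjusted p was 0.138, and the median ran from -1.42 to -0.82 without each library in turn.

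No list score passed in these 4 time comparisons, and edgeR called 0 genes in each. The counts at an unadjusted p under 0.05 were 315 in sham to day 14, 3259 in sham to day 21, 487 in SNI to day 14 and 623 in SNI to day 21. DESeq2 called 2, 33, 1 and 8 genes and voom with quality weights 1780, 0, 14 and 1371, in that order. Without sham day 21 replicate 2 the sham change to day 21 called 8333 genes, and a fit of the 2 groups alone called 11 in sham to day 14.

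The time course libraries differed along 1 shared axis, which carried 63.7% of the variance of log2 CPM. Sham day 21 replicate 1 had a score of 141 on it and a TMM factor of 0.633, and SNI day 7 replicate 2 a score of 132 and a TMM factor of 0.761; the 50 largest genes took 28.2% and 24.8% of their counts. Scores were over 0 in 6 of 9 SNI libraries and 1 of 8 sham libraries. Without both low-factor libraries, 0 genes were called in each of the 9 time course tests.

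**Figure D2:**
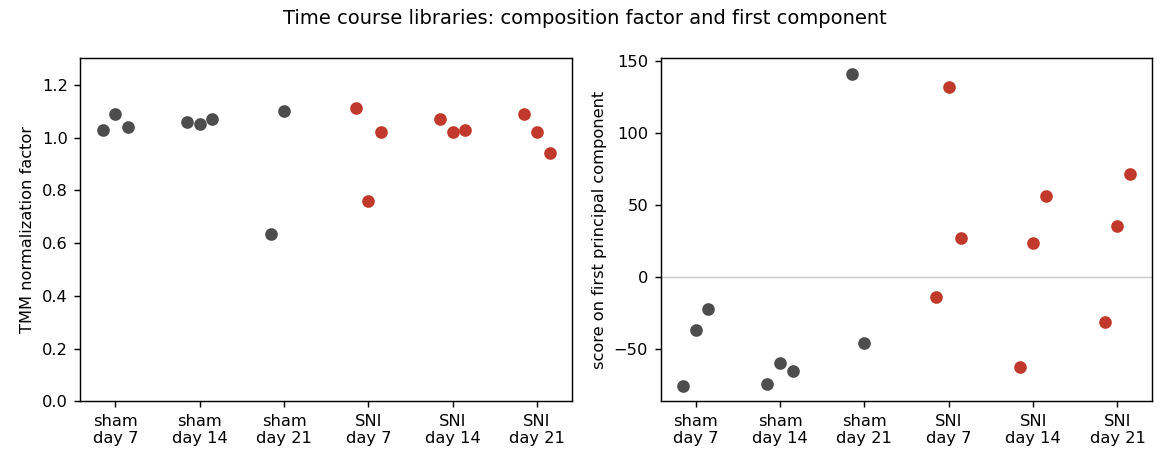
TMM normalization factor (left) and score on the first principal component (right) of the 17 time course libraries, a point per library, by group. Sham day 21 replicate 1 and SNI day 7 replicate 2 lie apart, with factors of 0.633 and 0.761.

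The second set addresses how amputated SNI digits differ from unamputated SNI digits. Averaged over days 7 and 14, the score of Schwann cell injury-response genes rose and that of myelin genes fell in the amputated digits. The injury-response score rose by 0.75 (95% interval 0.57 to 0.93, adjusted p = 0.00012 by limma, 6 libraries against 6), with 5 of 14 genes called higher and 0 lower, 6 higher and 2 lower when adjusted over the list alone. The median fold change of the list was only 0.13, from 0.01 (7 positive and 7 negative, without unamputated day 14 replicate 1) to 0.46 over the fits without 1 library. Gap43 (ENSMUSG00000047261) was at 4.72 CPM ± 1.0 (SD, n = 6) in amputated and 0.463 CPM ± 0.10 (SD, n = 6) in unamputated digits, a log2 fold change of 3.34 ± 0.20 (SE, adjusted p = 4.82e-06). Fgf5, a secreted growth factor, rose by 3.27 ± 0.28 (SE) on the log2 scale, and Sox2, a transcription factor of immature Schwann cells, by 2.51 ± 0.18. The myelin score fell by 1.45 (95% interval -1.88 to -1.02, adjusted p = 0.000423 by limma), with 11 of 17 genes called lower and 0 higher, and 13 lower and 1 higher when adjusted over the list alone. Mag, Mbp and Pmp22, proteins of the myelin sheath, had log2 fold changes of -2.67 ± 0.33, -1.44 ± 0.16 and -0.78 ± 0.075 (SE). The Schwann cell identity list split, with 3 of 10 genes called higher and 3 lower and a median of 0.03. Ngfr (ENSMUSG00000000120), the low-affinity neurotrophin receptor of denervated Schwann cells, rose by 2.51 ± 0.14 (SE, adjusted p = 4.82e-06), Foxd3 by 1.26 ± 0.15 and Cdh19 by 1.14 ± 0.13, while Scn7a had a log2 fold change of -0.87 ± 0.13. The score of that list rose by 0.25 (95% interval 0.10 to 0.40, adjusted p = 0.0215). The myelin and injury-response scores passed without each of the 12 libraries in turn. The identity call ended without amputated day 7 replicate 3, amputated day 14 replicate 1 or 3, unamputated day 7 replicate 2 or unamputated day 14 replicate 1 (up to 0.0675), and with a replicate block (0.118).

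**Figure D3:**
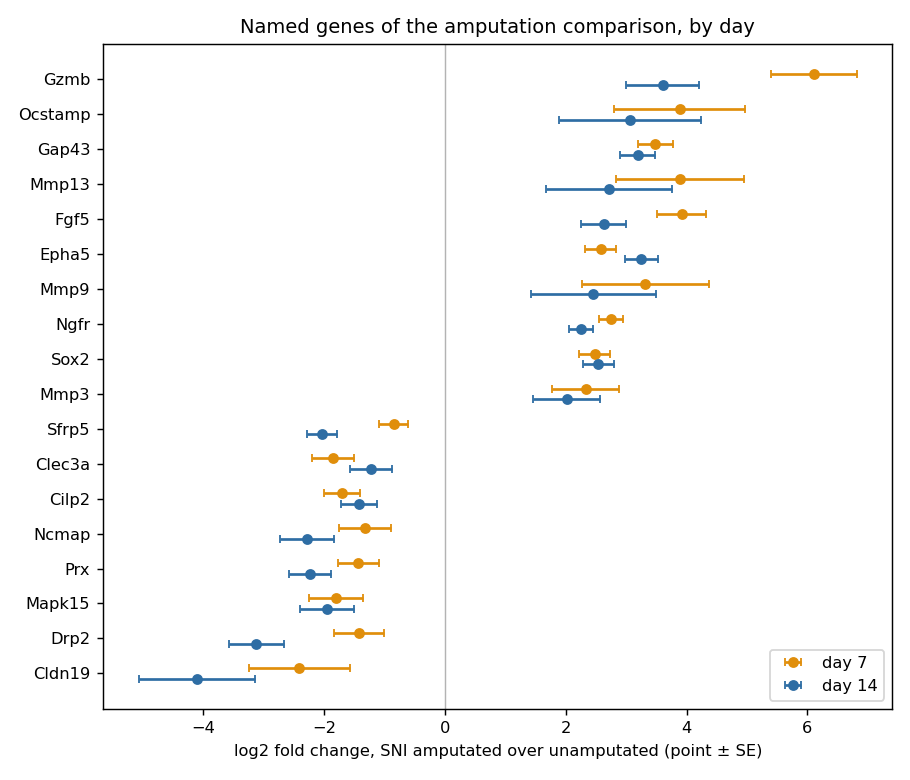
Log2 fold change of SNI amputated over unamputated digits (point, with the SE as bar) for 18 named genes at day 7 and day 14, ordered by their average. Gap43, at 3.48 and 3.19, and Cldn19, whose average was -3.25, lie near the opposite ends.

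Of the skeletal lists, the osteoblast and osteocyte score rose by 0.86 (95% interval 0.43 to 1.28, adjusted p = 0.0157 by limma), with 5 of 15 genes called higher and 1 lower, and 10 higher and 1 lower when adjusted over the list alone. Runx2, the transcription factor that sets osteoblast fate, rose by 1.76 ± 0.25 (SE) on the log2 scale and Dmp1, a matrix protein of osteocytes, by 1.67 ± 0.29, while Smpd3 had a log2 fold change of -0.39 ± 0.072. The osteoclast score rose by 1.32 (95% interval 0.53 to 2.10, adjusted p = 0.0215), with 4 of 12 genes called higher, 8 when adjusted over the list alone, and Ocstamp at 3.48 ± 0.80 (SE), Mmp9 at 2.89 ± 0.73 and Acp5 at 1.22 ± 0.29. That call ended without unamputated day 7 replicate 2 (adjusted p = 0.0564), with a replicate block (0.104) and with 1 surrogate variable (0.437). Collagenase Mmp13 rose by 3.31 ± 0.75 (SE) and Mmp3, a stromelysin, by 2.18 ± 0.39. Without unamputated day 7 replicate 1 or 2 or any unamputated library of day 14 the calls of Ocstamp, Mmp13 and Mmp9 ended, with a highest adjusted p over all fits without 1 library of 0.0625, 0.066 and 0.0862. Those of Mmp13 and Mmp9 also ended without amputated day 14 replicate 3, and that of Mmp9 without amputated day 7 replicate 1 or amputated day 14 replicate 1 or 2. The blastema mesenchyme score rose by 0.29 (95% interval 0.07 to 0.51, adjusted p = 0.0478), with Tnc at 0.95 ± 0.16 (SE) and Lhx9 at 0.66 ± 0.19 the 2 of 14 genes called higher, also 2 when adjusted over the list alone. Removing any 1 of 11 of the 12 libraries, all except amputated day 14 replicate 2, ended that call (adjusted p up to 0.135), as did a replicate block (0.118) and 1 surrogate variable (0.354).

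Endothelial genes rose, with a score difference of 0.37 (95% interval 0.17 to 0.56, adjusted p = 0.017 by limma), 6 of 12 genes called higher and 8 when adjusted over the list alone. Cldn5, a tight junction protein, rose by 0.58 ± 0.070 (SE) on the log2 scale and Vwf by 0.61 ± 0.11. The erythroid score rose by 0.93 (95% interval 0.37 to 1.49, adjusted p = 0.0215), with 1 of 6 genes called, Slc4a1 of the red cell membrane at 1.58 ± 0.28 (SE), and 6 when adjusted over the list alone. The adipocyte score rose by 0.34 (95% interval 0.10 to 0.57, adjusted p = 0.038), with 3 of 10 genes called higher and 1 lower, and 5 and 1 when adjusted over the list alone; Lpl was at 0.40 ± 0.086 (SE) and Plin4 at -0.60 ± 0.11. Differentiated epidermis genes fell, with a score difference of -0.28 (95% interval -0.44 to -0.13, adjusted p = 0.017), 6 of 15 genes called lower and 9 when adjusted over the list alone. Krt1 and Krt10, keratins of the upper epidermis, had log2 fold changes of -0.78 ± 0.081 and -0.34 ± 0.058 (SE), and Krt9 of palm and sole skin of -0.69 ± 0.074. The sweat gland score fell by 0.23 (95% interval -0.38 to -0.07, adjusted p = 0.038), with Aqp5 at -0.42 ± 0.061 (SE) and Foxi1 at -0.81 ± 0.19 called lower and Krt19 at 0.63 ± 0.13 called higher, and the same counts when adjusted over the list alone. The erythroid call ended without any 1 of 4 libraries, amputated day 7 replicate 1 or 3, unamputated day 7 replicate 2 or unamputated day 14 replicate 1 (adjusted p up to 0.0575). The adipocyte call ended without any 1 of 8 libraries and the sweat gland call without any 1 of 10 (up to 0.0973 and 0.099). The adipocyte call stood only without amputated day 14 replicate 1 or 3, unamputated day 7 replicate 1 or unamputated day 14 replicate 1, and the sweat gland call only without amputated day 14 replicate 3 or unamputated day 7 replicate 3. With a replicate block the epidermis, adipocyte and sweat gland calls ended (adjusted p of 0.102, 0.118 and 0.12), and with 1 surrogate variable these (0.182, 0.222 and 0.44) and the erythroid call (0.354).

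**Figure D4:**
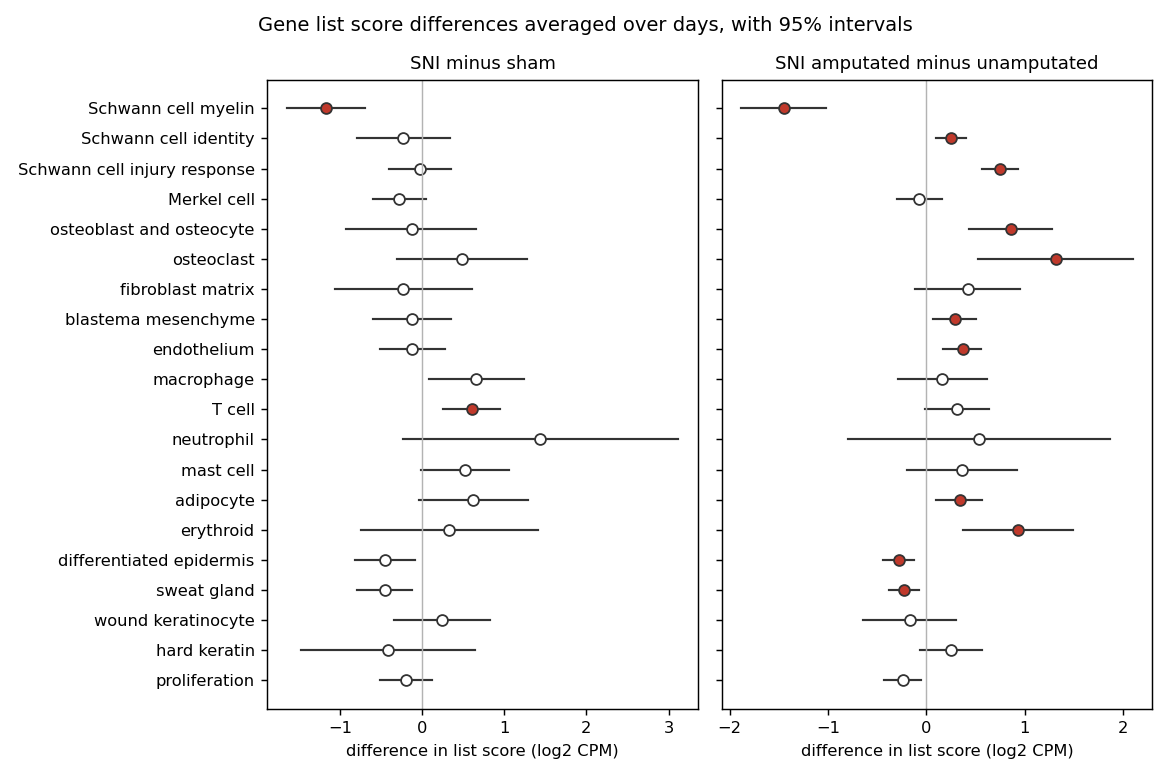
Difference in list score (mean log2 CPM of the list's genes; point, with the 95% interval as line) for 20 lists, averaged over days, for SNI minus sham (left) and SNI amputated minus unamputated (right); filled points have an adjusted p under 0.05. The myelin list is at -1.17 and -1.45.

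In the average, camera called 14 of the 38 lists, 11 up and 3 down, and 0 with an estimated correlation. For the myelin and injury-response lists the adjusted p was 8.02e-19 and 2.21e-06, with an adjusted p = 0.0615 with an estimated correlation for each. Fibroblast matrix genes were up by camera, with 11 of 12 positive and a median of 0.51 (adjusted p = 0.00672, adjusted p = 0.68 with an estimated correlation), a call that ended without amputated day 7 replicate 1 (adjusted p = 0.0506, median 0.34). Proliferation genes were down by camera, with 14 of 15 negative, a median of -0.16, 4 genes called lower and 7 when adjusted over the list alone (adjusted p = 0.000562, adjusted p = 0.542 with an estimated correlation), and the median ran from -0.25 to -0.13 without each library in turn. Mki67, a marker of cycling cells, had a log2 fold change of -0.78 ± 0.19 (SE). Mitochondrial transcripts and hard keratin genes were also up by camera, with medians of 0.15 and 0.18 (adjusted p = 0.811 and adjusted p = 0.711 with an estimated correlation). Each call ended without amputated day 7 replicate 2, amputated day 14 replicate 1, unamputated day 7 replicate 1 or 2 or unamputated day 14 replicate 2, with adjusted p up to 0.192 and 0.153 and medians down to 0.09 and 0.01 over the fits without 1 library. The mitochondrial call also ended without amputated day 14 replicate 2 or unamputated day 14 replicate 1. Neuronal transcripts, Merkel cell, cartilage, tendon, macrophage, neutrophil, T cell, B cell, mast cell, skeletal muscle and wound keratinocyte scores did not pass.

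The average over days called 2060 of 17475 genes by edgeR, 998 higher and 1062 lower; DESeq2 called 3066 and voom with quality weights 3188. The named genes, for which every amputated library lay on the same side of every unamputated library within each day, included Gzmb, a granzyme of cytotoxic lymphocytes, at 4.86 ± 0.47 (SE) on the log2 scale, and Epha5, an ephrin receptor, at 2.92 ± 0.19. Gzmb was at only 0.0808 CPM ± 0.05 (SD, n = 6) in unamputated digits, against 2.15 CPM ± 1.3 (SD, n = 6) in amputated ones. The size of its rise is therefore uncertain. Among the lower ones were Cldn19 (-3.25 ± 0.64), Drp2 (-2.27 ± 0.31), Prx (-1.83 ± 0.24) and Ncmap (-1.79 ± 0.31) of myelinating Schwann cells. Mapk15 (-1.87 ± 0.31), Cilp2 (-1.56 ± 0.21), Clec3a (-1.53 ± 0.24) and Sfrp5 (-1.44 ± 0.17) were also lower. The count fell below the reported one by more than 1.5 times without 7 of the 12 libraries: 746 without unamputated day 7 replicate 1, 980 without its replicate 2, and 1280 without amputated day 7 replicate 1. It was 1303 without amputated day 14 replicate 3 and 1264, 1067 and 939 without unamputated day 14 replicates 1, 2 and 3. With replicate number as a block it was 284, and with 1 surrogate variable 156.

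At day 7, the injury-response score rose by 0.84 (95% interval 0.59 to 1.10, adjusted p = 0.000935 by limma) and the identity score by 0.40 (95% interval 0.18 to 0.61, adjusted p = 0.0133). The erythroid score rose by 1.65 (95% interval 0.85 to 2.44, adjusted p = 0.0133). The myelin score fell by 1.14 (95% interval -1.75 to -0.53, adjusted p = 0.0133). Ngfr was at 54.1 CPM ± 11 (SD, n = 3) in amputated and 7.99 CPM ± 1.6 (SD, n = 3) in unamputated digits, a rise of 2.76 ± 0.20 (SE) on the log2 scale. Gzmb rose by 6.11 ± 0.71 (SE), Fgf5 by 3.92 ± 0.41, Gap43 by 3.48 ± 0.29, Slc4a1 by 2.84 ± 0.42 and Runx2 by 1.79 ± 0.35. Gzmb was at 2.73 CPM ± 1.6 (SD, n = 3) in amputated and 0.0369 CPM ± 0.018 (SD, n = 3) in unamputated digits. So low a level leaves the size of its rise uncertain. Rptn and Sprr1b, proteins of the cornified cell envelope, had log2 fold changes of -3.06 ± 0.59 and -1.82 ± 0.25, and Lce3c of -1.61 ± 0.27. The Rptn call ended without any 1 of the 6 libraries (adjusted p up to 0.134), the Runx2 call without any except amputated replicate 3 (up to 0.14), and the Lce3c call without amputated replicate 1 or 2 (up to 0.0729). The osteoclast score rose by 1.65 (adjusted p = 0.0385), the adipocyte score by 0.63 (adjusted p = 0.0133) and the endothelial score by 0.49 (adjusted p = 0.0179), and the differentiated epidermis score fell by 0.41 (adjusted p = 0.0133). Without amputated day 7 replicate 1 the myelin, epidermis, endothelial and osteoclast calls ended (adjusted p of 0.0606 for myelin, 0.0566 for epidermis, 0.075 for endothelium and up to 0.144 for osteoclast); the osteoclast call also ended without unamputated day 7 replicate 1 or 2. With a replicate block all the day 7 score calls except injury response and erythroid ended (adjusted p from 0.0668 to 0.116), and with 1 surrogate variable the myelin (0.0581), epidermis (0.0517) and osteoclast (0.133) calls. Camera called 17 of the 38 lists, 11 up and 6 down, and 0 with an estimated correlation, the smallest being an adjusted p = 0.0768 with an estimated correlation.

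The other named genes of day 7 were Epha5 (log2 fold change 2.58 ± 0.26, SE), Sox2 (2.48 ± 0.26), Msmp (2.02 ± 0.31) and Ccl19 (1.86 ± 0.32), which rose. Clec3a (-1.85 ± 0.34), Lair1 (-1.82 ± 0.40), Mstn (-1.73 ± 0.32), Cilp2 (-1.70 ± 0.30), Islr2 (-1.39 ± 0.25) and Fxyd2 (-1.28 ± 0.22) fell. In all, edgeR called 236 genes at day 7, 105 higher and 131 lower, DESeq2 723 and voom with quality weights 371. The count was 115 without amputated day 7 replicate 1, 117 without its replicate 2, and 83, 125 and 98 without unamputated day 7 replicates 1, 2 and 3. It was 57 in a fit of the 2 groups alone and 38 with a replicate block. Of the 20 named genes, 9 kept their call without each library in turn; the largest loss, 10 genes, came without amputated day 7 replicate 2.

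At day 14, the myelin score fell by 1.76 (95% interval -2.37 to -1.15, adjusted p = 0.00306 by limma), with 11 of 17 genes called lower and 14 when adjusted over the list alone. Drp2 was at 1.34 CPM ± 0.60 (SD, n = 3) in amputated and 11.7 CPM ± 0.89 (SD, n = 3) in unamputated digits, a log2 fold change of -3.12 ± 0.46 (SE). Prx, which codes for periaxin, had a log2 fold change of -2.23 ± 0.35, Ncmap of -2.27 ± 0.45 and Mbp of -1.80 ± 0.23. The injury-response score rose by 0.66 (95% interval 0.41 to 0.92, adjusted p = 0.00338), with Gap43 up by 3.19 ± 0.29 (SE), Fgf5 by 2.63 ± 0.37 and Sox2 by 2.54 ± 0.26. The osteoblast and osteocyte score rose by 1.03 (95% interval 0.43 to 1.64, adjusted p = 0.044), with 4 of 15 genes called higher and 8 when adjusted over the list alone. That call stood only without amputated day 14 replicate 2 and ended without any 1 of the other 5 libraries (up to 0.251), and with a replicate block (0.129). Cthrc1, a secreted protein of matrix-forming fibroblasts, rose by 3.45 ± 0.67 (SE), Dmp1 by 1.76 ± 0.41 and Runx2 by 1.74 ± 0.35. Without amputated day 14 replicate 3 the calls of Cthrc1, Dmp1, Runx2, Drp2, Prx and Ncmap ended. Those of Cthrc1, Dmp1, Runx2 and Ncmap also ended without any 1 unamputated library, those of Dmp1, Runx2 and Ncmap without amputated replicate 1, and that of Prx without unamputated replicate 2 or 3. The highest adjusted p of these genes over all such fits was 0.142. Fibroblast matrix genes had 12 of 12 positive with a median of 0.92 and 6 higher when adjusted over the list alone, 0 over all genes (camera adjusted p = 5.25e-06, adjusted p = 0.962 with an estimated correlation). Camera called 9 of the 38 lists, and the myelin list had an adjusted p = 0.105 with an estimated correlation, the smallest.

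The other named genes of day 14 were Epha5 (log2 fold change 3.25 ± 0.27, SE), Ngfr (2.25 ± 0.20), Sema4f (1.63 ± 0.22) and Zfp607b (1.56 ± 0.31), which rose. Sfrp5 (-2.03 ± 0.25), Mapk15 (-1.94 ± 0.45), Dennd1c (-1.92 ± 0.30), Doc2g (-1.85 ± 0.37), Aatk (-1.76 ± 0.29) and Sptbn5 (-1.66 ± 0.37) fell. In all, edgeR called 481 genes at day 14, 230 higher and 251 lower, DESeq2 1858 and voom with quality weights 2212. The count was 145 without amputated day 14 replicate 2, 32 without its replicate 3, and 74, 45 and 33 without unamputated day 14 replicates 1, 2 and 3. It was 9 with a replicate block and 12 with 1 surrogate variable. Of the 20 named genes, 8 kept their call without each library in turn; the largest loss, 12 genes, came without amputated day 14 replicate 3.

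Both days called the same 44 genes higher, against 1.4 expected by chance, and the same 35 lower, against 1.9. These expectations treat genes as independent. Both contrasts came from 1 fit with shared dispersions, so the expectations can be too low. Across genes the fold changes of the 2 days correlated with a Pearson r of 0.37, from 0.26 to 0.43 without each library in turn. The test of whether the amputation effect differed between days called 0 genes by edgeR, with 1092 at an unadjusted p under 0.05, 18 by DESeq2 and 0 by voom with quality weights.

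From day 7 to day 14, hair and nail keratin genes rose in amputated SNI digits. The hard keratin score rose by 1.01 (95% interval 0.56 to 1.46, adjusted p = 0.0192 by limma), with 12 of 12 genes positive, 1 called and 10 higher when adjusted over the list alone. The call ended without amputated day 7 replicate 1 or 3 or amputated day 14 replicate 1 (adjusted p up to 0.111). Krt32 rose by 1.86 ± 0.20 (SE) on the log2 scale. The keratin-associated proteins Krtap5-1 (2.43 ± 0.36), Krtap29-1 (2.36 ± 0.32), Krtap5-4 (2.35 ± 0.38), Krtap5-3 (2.30 ± 0.38) and Krtap5-5 (2.24 ± 0.31) rose most among the named genes. Their sequences are alike, and how reads shared between them were counted is not known. Plin4 (-0.94 ± 0.16), Grk3 (-0.79 ± 0.15), Csf2rb2 (-0.69 ± 0.13) and Arhgap45 (-0.60 ± 0.11) fell. In unamputated digits Krtap29-1 rose by 2.07 ± 0.32 (SE), Krtap5-5 by 1.94 ± 0.31, Ctse by 1.83 ± 0.31, Krt40 by 1.80 ± 0.27 and Krtap10-10 by 1.78 ± 0.31. The hard keratin score there differed by 0.67 (95% interval 0.22 to 1.11, adjusted p = 0.285), with Krt32 called. By camera the list had an adjusted p = 0.149 in amputated and an adjusted p = 0.405 in unamputated digits with an estimated correlation.

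In this time comparison edgeR called 106 genes in amputated digits, 101 higher and 5 lower, and 53 in unamputated digits, all higher. In both, 50 genes were higher, against 0.31 expected if genes were independent. Keratin-associated genes alike in sequence were among them, and both contrasts came from 1 fit, so that expectation can be too low. DESeq2 called 451 and 147 and voom with quality weights 92 and 127. The amputated count was 3 without amputated day 7 replicate 2 and 17 without its replicate 3. The unamputated count was 0 without unamputated day 7 replicate 1 or 2 or unamputated day 14 replicate 1 or 3, and 31 without unamputated day 7 replicate 3. Of the named genes, 0 of 9 in amputated and 0 of 5 in unamputated digits kept their call without each library in turn. All 9 lost it without amputated day 7 replicate 2, and all 5 without unamputated day 14 replicate 1.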

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

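Of the tests in this part, those of length, of the 50 largest genes and of the shared gradient were set before their results were seen, and the other tests of explanations and all the splits were chosen only after the result was seen.

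Camera tested the difference between days itself for each list. It called 6 lists up and 4 down for day 14 minus day 7 of the SNI effect. For day 21 minus day 7 it called 5 up and 2 down, and for the amputation effect 7 up and 9 down. A called list was singled out where its unadjusted p with an estimated correlation was also under 0.05. None of these differences passed with an estimated correlation after adjustment. In the time course, day 14 minus day 7 of the SNI effect, the median difference was 0.79 for myelin genes (adjusted p = 4.23e-06, adjusted p = 0.288 with an estimated correlation), 2.40 for osteoclast genes (6.83e-14 and 0.246) and -0.79 for adipocyte genes (1.43e-05 and 0.288). It was -4.30 for neutrophil genes (1.48e-10 and 0.248), 1.81 for inflammatory cytokine genes (3.93e-07 and 0.246) and 0.55 for immediate early and heat shock genes (2.23e-13 and 0.0862). The neutrophil median of the SNI effect at day 7 was 6.73, and 1.04 without SNI day 7 replicate 2. Day 21 minus day 7, it was 1.03 for immediate early and heat shock genes (0.000127 and 0.799). In the amputation effect, day 14 minus day 7, it was 0.84 for wound keratinocyte genes (3.63e-06 and 0.33), -0.61 for adipocyte genes (6.28e-07 and 0.33), -1.17 for mast cell genes (7.58e-08 and 0.33) and -1.32 for erythroid genes (7.58e-08 and 0.33).

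The time course libraries spread along 1 axis with 63.7% of the variance, led by sham day 21 replicate 1 and SNI day 7 replicate 2. Without the 50 largest genes the axis still carried 63.6%. As 50 of 16084 genes weigh little in log2 CPM, that could hardly change, so it does not decide on dominant genes. The TMM factors of the 2 leading libraries then were 0.664 and 0.771. Their low factors thus did not rest on these genes alone. Depth as the main source is argued against by a Spearman rho of -0.10 over 17 libraries (p = 0.7 by permutation). The Pearson r was -0.18, and -0.30 without the 2 farthest libraries, so a weaker relation stays open. Gene loadings went with transcript length at a Spearman rho of -0.61 (-0.30 for the amputation table), from a median loading (times 1000) of 6.28 for the shortest transcripts to -8.3 for the longest, so RNA degradation or length bias may account for part of it. Whether nerve injury moved the axis cannot be decided with so few libraries. SNI minus sham was 47.6 against an SD of 69, with an exact p of 0.168 over 4000 assignments within days. Length bias or degradation, nerve injury and dominant genes remain open for this axis. In the amputation set the first axis carried 22.2% of the variance. All its unamputated libraries had negative scores (-35.2 to -8.23). Amputated libraries scored 10.6 to 42.1, except day 7 replicate 3 at -2.3. That axis nearly separated the groups, so the rho of -0.30 leaves length bias or degradation open for part of the amputation differences. The calls of that set were not tested against length.

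In amputated against unamputated SNI digits, the myelin score was lower and the injury-response score higher. Fewer Schwann cells are argued against as the whole cause of both changes, since the 10 identity genes went both ways. Their median log2 fold change was 0.03 (SD 1.11, lowest -1.23) against -1.42 for myelin genes. The identity list holds Ngfr, a receptor of denervated Schwann cells, so its median does not measure cell number. A loss of cells stays open. Amputation alone stays open, since no sham unamputated group exists and the SNI effect on the myelin score among amputated digits (upper bound -0.70) does not address it. Whether unamputated digits kept their nerve supply is also open. The SNI and amputation effects correlated with an r of 0.93 over 41 genes of the Schwann cell lists, 33 with the same sign, against 0.52 over all 14863 shared genes, but the myelin genes that show the pattern are among them, and the injury-response score differed by -0.03 (95% interval -0.41 to 0.35) for SNI against 0.75 (95% interval 0.57 to 0.93) for amputation.

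The SNI effect on myelin genes was smaller at day 14 than at day 7 by a median of 0.79, which did not pass with an estimated correlation (adjusted p = 0.288), and day 14 was not tested against day 21. The shared axis of the libraries is argued against as its whole source, since 0.947 of the difference between days in the myelin score stayed with the surrogate variable (0.89 without it, 0.84 with it). A general recovery of myelin transcripts by day 14 stays open, since the 2 sets went opposite ways. In amputated SNI digits of the second set, the myelin median from day 7 to day 14 was -0.64 (-0.76 to -0.15 without each library in turn). In SNI digits of the time course it was 1.05 (0.56 to 1.49). Recovery would give a rise in both, and neither camera call held with an estimated correlation. At day 21 of the time course the median SNI effect was -1.69 (-1.83 to -1.51 without each library in turn). That argues against a recovery lasting to day 21 in the time course. A recovery confined to day 14 of the time course stays open. The lower myelin score of amputated digits (upper bound -1.15) does not address recovery, since both groups of the second set had SNI. Chance, an incomplete injury in some animals and a wrong label also stay open.

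Other splits of the same libraries were fitted in the same way. For the SNI comparison of day 7 and of day 14 and for the time changes of sham and SNI to day 14 and of SNI to day 21, the 10 splits of each are too few for a share under 0.05; the real value was 0 and the highest other 0. The same holds for amputation at day 7 (real 236, highest other 301), amputation at day 14 (481 and 1), the time change of amputated digits (106 and 136) and of unamputated digits (53 and 0), where 2, 1, 2 and 1 of 10 splits called as many. For the SNI average all 100 splits called at least the real 0, and the highest of the others called 9885. That points to a strong structure of the samples that does not follow the surgery labels alone. Whether surgery is part of it was not settled. For the SNI interaction 100 of 100 called at least the real 0, with a highest other of 0. A real count of 0 is reached by every split, so these counts say nothing on chance. For the amputation average 1 of 100 splits, the real one, called 2060 and the highest other 25. Chance is argued against there but, with only 100 splits, not excluded. For the amputation interaction 100 of 100 likewise called at least the real 0, and the highest other, 2060, is the average with the labels of 1 day exchanged.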

How the results depend on the processing

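Chosen only after the result was seen were the tests with 1 surrogate variable, with both libraries of a low TMM factor left out, and with days 7 and 21 only. Of 158 list calls by camera, 157 ended with an estimated correlation, 138 with fry, 3 with RLE, 5 with no filter and 10 with a replicate block. With the surrogate variable 55 ended and 4 reversed, without both libraries of a low TMM factor 27 ended and 6 reversed of 98, and with days 7 and 21 only 9 of 16 ended. Of 1197 fits without 1 library, 995 kept the call, 194 lost it and 8 reversed its sign. Correlations of fold changes between comparisons moved in 28 of 81 such fits and in 5 of 5 without both libraries of a low TMM factor. Of 25 score calls, 24 stood with RLE, 11 with a replicate block and 16 with the surrogate variable. Of the 74 calls of named genes in the amputation set, counted once per comparison, 70 stood with voom, 57 without a filter, 38 with a replicate block and 39 with the surrogate variable. At day 7 of the time course the self-test, in which genes varied independently, recovered 8.96% of 2-fold changes. Under that condition most changes of that size would be missed in that contrast. The other days and the average were not simulated. Except where libraries or covariates were taken out by construction, the cause was not tested.

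In the order SNI against sham at day 7, day 14, day 21 and averaged, interaction, sham to day 14 and day 21, and SNI to day 14 and day 21, DESeq2 called 40, 61, 12, 153, 1, 2, 33, 1 and 8 genes where edgeR called 0. Voom with quality weights called 7749 at day 7, 8737 at day 14, 21 in the interaction, 1780 in sham to day 14, and 14 and 1371 in SNI to days 14 and 21. In the amputation set DESeq2 called 723 at day 7, 1858 at day 14, 18 in the interaction, and 451 and 147 in the time changes; voom called 371, 2212 and 3188 at day 7, day 14 and averaged, and 127 in the unamputated time change. The groups alone gave 11 in sham to day 14, 57 for amputation at day 7, and 70 and 6 in the time changes. The surrogate variable of the amputation set, which largely aligned with amputation, gave 12 at day 14, 156 averaged, and 176 and 27 in the time changes. That of the time course gave 5 in the SNI average. No filter gave 21 in the unamputated time change.

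Replicate numbers did not pair the libraries of the amputation set, where those of the same number correlated at -0.203 to 0.022 (0 of 6 pairs over 0.1). In the time course 5 of 8 same-number pairs were over 0.1. They were at 0.387, 0.241 and -0.0933 on day 7 and 0.243, 0.147 and 0.105 on day 14. Pairs of different number ran from -0.398 to 0.269 and from -0.236 to 0.15 on these days. At day 21 the 2 sham libraries deviate from their mean in mirror image, so the values there, down to -0.787, do not address pairing. Whether replicates of the time course were paired stays open. In the amputation set a replicate block called 38 genes at day 7, 9 at day 14 and 284 averaged. It called 104 in the unamputated time change. Of these calls, 37, 8, 276 and 52 were shared with the reported ones, in that order.

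Without each library in turn, the counts ran from 0 to 152 for SNI at day 21, 0 to 2 averaged, 0 to 3439 in the interaction and 0 to 8333 in sham to day 21. They ran from 83 to 179 for amputation at day 7, 32 to 501 at day 14, 746 to 2463 averaged, 3 to 117 in the amputated and 0 to 65 in the unamputated time change. Adjusted p values of lists whose sign reversed in such a fit ran from 5.46e-05 to 0.78 for T cell genes at day 21 and 1.86e-07 to 0.813 for macrophage genes in the amputated time change. In SNI to day 21 they ran from 0.000236 to 0.74 for myelin, 4.1e-09 to 0.269 for osteoblast, 1.63e-07 to 0.655 for cartilage, 6.23e-08 to 0.803 for fibroblast matrix, 0.000604 to 0.811 for BMP pathway and 0.000169 to 0.547 for macrophage genes. With the surrogate variable the sign reversed for Wnt genes at day 7 (0.772), cartilage genes at day 14 (0.872) and averaged (0.866), and Wnt genes in sham to day 14 (0.675). Without both libraries of a low TMM factor it reversed for mast cell genes in sham to day 21 (0.914) and, in SNI to day 21, for osteoblast (0.283), cartilage (0.684), fibroblast matrix (0.853), BMP pathway (0.815) and macrophage genes (0.576).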

Other observations

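The neuronal and neurotrophic factor lists were tested in the amputation set, and no test of this part was chosen only after the result was seen. Averaged over days, Uchl1, a ubiquitin hydrolase abundant in neurons, rose in amputated SNI digits by 1.24 ± 0.20 (SE) on the log2 scale (adjusted p = 0.00396 by edgeR), while Tubb3, the tubulin of neurons, had a log2 fold change of -0.61 ± 0.094 (adjusted p = 0.00337). The neuronal score differed by -0.08 (95% interval -0.32 to 0.15) and did not pass. Of 15 genes of neurotrophic and nerve-derived factors, 2 were called higher and 3 lower, and 3 and 4 when adjusted over the list alone; the score differed by 0.01 (95% interval -0.15 to 0.18). Gdnf, a growth factor for motor and sensory neurons, rose by 0.80 ± 0.17 (SE).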
